A study of Mus musculus with 4 samples.

How the data were processed

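Total RNA from the quadriceps of 4 mice was measured on Affymetrix whole-transcript expression arrays, 1 array per sample. The labels give 2 groups of 2 arrays: wild-type mice (WT) and mice carrying transgenes for both NF90 and NF45 (double transgenic, dbTg). NF45 is encoded by Ilf2. In both groups replicate 1 was male and replicate 2 was female, so the arrays of a group came from different animals. WT replicate 1 was 17 to 18 weeks old and the other 3 mice were 16 weeks old. The number of arrays limits the precision of every value.

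The deposited values are RMA expression values on the log2 scale, made with Affymetrix Expression Console, per the labels and the submitters' processing notes. RMA corrects the background of each array, normalizes the arrays by quantiles and summarises the probes of each probe set. The version of the software and the build behind the array's annotation are not given in the sources used here. No call of presence or absence accompanies the values used here, so no background floor was set. Over all 41345 probe sets the array medians were 1.60 (WT 1), 1.58 (WT 2), 1.55 (dbTg 1) and 1.57 (dbTg 2). The upper quartiles were 2.80, 2.78, 2.99 and 2.98 in the same order.

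Of the 41345 probe sets, 23521 were paired with exactly 1 gene symbol, 1814 with several and 16010 with none in the annotation used here. Symbols were matched through Entrez identifiers to a RefSeq gene table of assembly GRCm38.p6 for 23328 probe sets, and 0 symbols changed. Probe sets with several symbols or none were named after no gene. A gene was represented by its probe set with the highest mean over all 4 arrays, which gave 22180 genes, 1082 of them with more than 1 probe set. Genes whose mean over the 4 arrays lay at or above the 40th percentile, 1.48 on the log2 scale, were tested, which left 13308. Ddx3y was not analysed here, and another gene that the naming rule below covers is not reported here.

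Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend; 2 residual degrees of freedom per gene and 4.76 added from the spread of all genes). Tests were two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. A positive difference means higher in dbTg. Standard errors (SE) are the moderated ones from limma, and SDs are over the 2 arrays of a group. With 2 arrays against 2, a permutation test cannot give a p-value below 0.333, so a count without a test was added: genes at least 1.5-fold apart in every pair of a dbTg and a WT array, beside the same count for the other splits of the 4 arrays.

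A set of 36 gene lists covering the transgene products, muscle programmes, metabolism, stress, RNA pathways, the cell types that quadriceps can hold and the sex of the mice was fixed before the data were examined. So were the groups, the tests and the other settings tried. The lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01 between genes, Benjamini-Hochberg adjusted over 33 lists. The transgene products, red blood cell markers and genes that check the sex labels were left out of this test. The lists were tested again with a correlation estimated from the arrays and with fry, which asks whether the genes of a list move one way on balance. With an estimated correlation the test rests on the 2 residual degrees of freedom. A call lost there is weak evidence against a shift of the list. Some genes stand in more than 1 list.

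The genes named in the text followed a rule, also fixed beforehand. It took the transgene products and, in each direction, the 12 genes with the largest change among those past the threshold whose groups did not overlap. Symbols of predicted genes and of microRNA or odorant receptor genes were left out of these 12. From each list it took up to 4 members past the threshold, or the 2 with the smallest p-values, and it added Dnm2, Mtm1 and the genes that check the sex labels. Other genes named in the text were chosen after their values were seen. They serve as examples of their lists.

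The procedure was tested on simulated data in 20 rounds, each with 200 of the 13308 tested genes changed. With spreads drawn from limma's prior, calls were made for 5.80% of the genes changed 2-fold, 83.3% of those changed 4-fold and 98.2% of those changed 8-fold, and 5.42% of all calls were false. With each gene given its own moderated SD, 59.9% of the 2-fold changes were called and 11.3% of calls were false. A list shifted by 1 on the log2 scale was called in all 20 rounds under both. The simulated genes varied independently of each other. The rounds therefore do not show how often genes or lists are falsely called when genes move together.

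The alternatives were leaving out each array, the replicate number as a block, median centring, quantile normalization, other intensity filters, the mean of a gene's probe sets, eBayes without a trend or with robust estimation, every probe set on its own, other thresholds and a plain t-test without moderation.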

Results

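Gene expression in the quadriceps of 2 WT and 2 NF90-NF45 dbTg mice was compared on whole-transcript arrays, to find which genes differ in muscle that carries both transgenes. Each group held 1 male (replicate 1) and 1 female (replicate 2). Across the 13308 tested genes, the arrays correlated with Pearson's r of 0.966 within WT, 0.981 within dbTg and 0.946 to 0.953 between groups (across genes, which are not independent replicates). The labelled sex matched the sex-linked genes. Xist, which is transcribed from the inactive X chromosome, read 1.74 and 1.79 on the log2 scale in the males and 6.66 and 7.23 in the females of the WT and dbTg groups. The Y-linked gene Eif2s3y read 5.76 and 5.78 in the males and 0.92 and 0.58 in the females.

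Ilf2, which encodes the transgene product NF45, was strongly higher in dbTg muscle. It rose from 5.04 ± 0.01 (SD, n = 2) to 10.26 ± 0.14 (SD, n = 2) on the log2 scale, a 37.4-fold difference (log2 difference 5.23, SE 0.14, limma adjusted p = 7.17e-05). Whether its probes read the transgene, the mouse gene or both is not given in the sources used here.

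Muscle of dbTg mice had higher RNA levels of part of the embryonic and denervation-linked muscle genes and of genes of macrophages and other leukocytes. It had lower RNA levels of Mstn and Mylk2, described below. Of the 12 named lower genes, only these kept their calls with the replicate number as a block. Lists of metabolic genes were lower with a preset correlation between genes, but not with an estimated correlation or under fry, and had 0 members past the threshold over all genes. In limma, 267 genes rose and 27 fell in dbTg among the 13308 tested, so 90.8% of the 294 called genes were higher. The difference reached 2-fold for 259 of the higher and 18 of the lower genes. At an unadjusted p under 0.05, 1866 genes were higher and 617 were lower, and after quantile normalization 1385 and 939. The balance changed with the level in WT: of the called genes at or above the 90th percentile of that level, 16 were higher and 17 lower. The groups did not overlap for 50% of all tested genes, where chance gives 33.3%. The count of calls depended on the array left out, with the lone array of a group assumed to vary like the other group. Without WT replicate 1, 610 genes were higher and 156 lower, and without WT replicate 2, 593 and 142. Without dbTg replicate 1 or without dbTg replicate 2, 4 were higher and 0 lower (343 and 247 lower at an unadjusted p under 0.05), and the 4 were Ilf2, Cd226, Ankrd1 and Ctss in both cases. Every other named gene described here as rising or falling lost its call without either dbTg array.

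**Figure D1:**
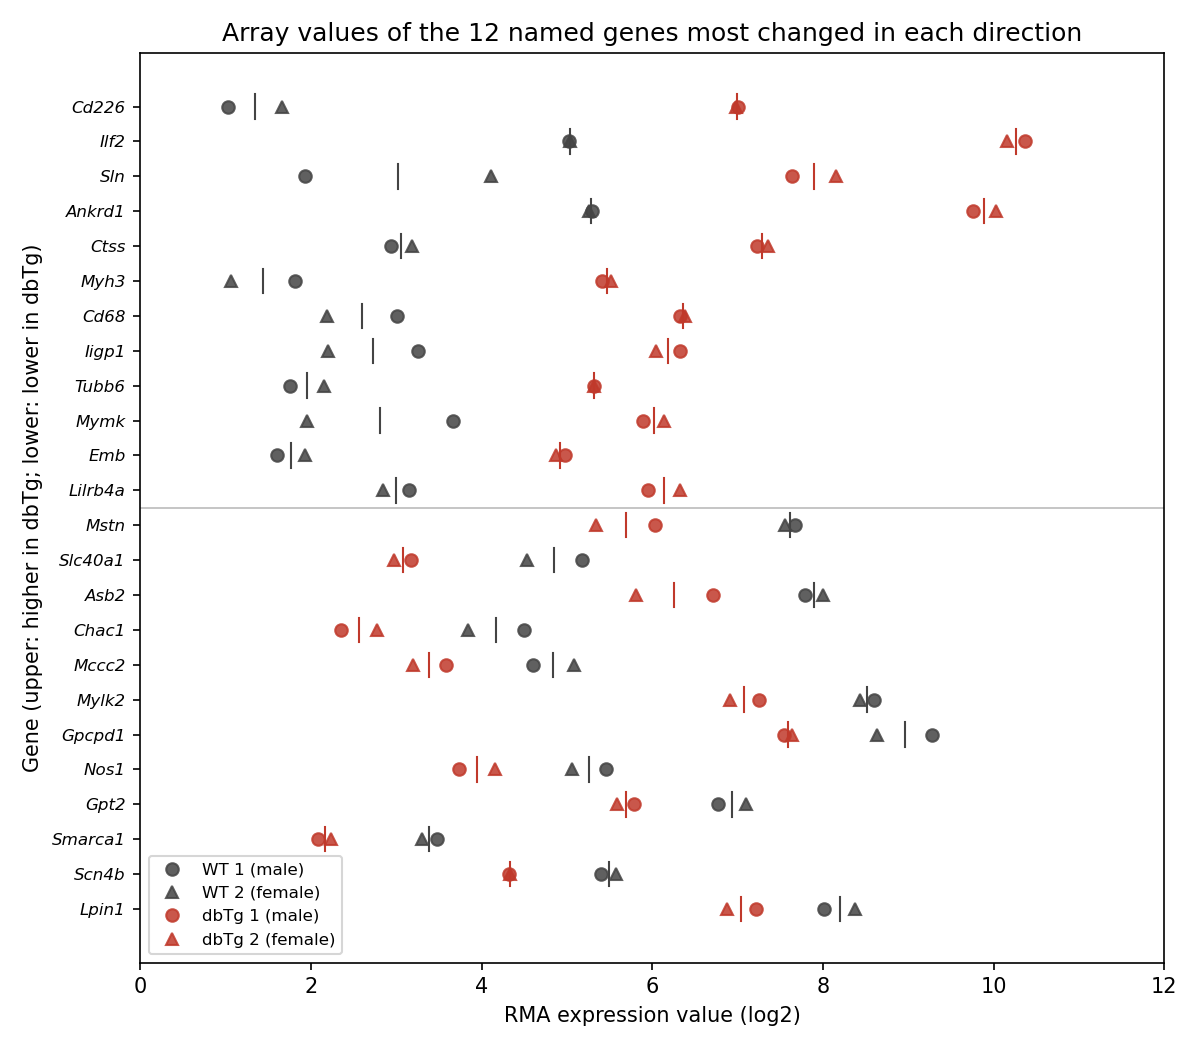
RMA expression values (log2, horizontal axis) of the 12 named genes most higher (upper part) and the 12 most lower (lower part) in dbTg quadriceps. Points are single arrays (circles male, triangles female) and short vertical lines are group means (n = 2). These genes were chosen among those whose groups do not overlap. Ilf2 moved from 5.04 to 10.26 and Mstn from 7.61 to 5.69.

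Cd226, an adhesion receptor known from T cells and natural killer cells, had the largest measured difference of the named genes, from a WT level under the intensity filter. It read 1.35 ± 0.45 (SD, n = 2) in WT, and 7.01 and 6.98 on the dbTg arrays (log2 difference 5.65, SE 0.26, adjusted p = 0.000494). Sln, the sarcolipin that inhibits the calcium pump of the sarcoplasmic reticulum, rose 29.3-fold (log2 difference 4.87, SE 0.63, adjusted p = 0.0213). Its WT arrays read 1.93 and 4.12, and its difference was 3.78 without WT replicate 1 and 5.96 without WT replicate 2. With robust eBayes its adjusted p was 0.0713, in a range of 1.1e-05 to 0.228 over all alternatives. Ankrd1, a stress-responsive ankyrin repeat protein of striated muscle, rose 24.5-fold (4.61, SE 0.15, adjusted p = 0.000119). Ctss, a lysosomal protease of antigen-presenting cells, rose 18.8-fold (4.23, SE 0.19, adjusted p = 0.000494), and Myh3, the embryonic myosin heavy chain, by 4.03 (SE 0.29, adjusted p = 0.00309), from a WT mean of 1.44 that lay under the intensity filter. The macrophage glycoprotein gene Cd68 rose by 3.76 and Lilrb4a, an inhibitory receptor of myeloid cells, by 3.14. Iigp1, an interferon-inducible GTPase, rose by 3.46. Tubb6, a beta-tubulin, rose by 3.37, Mymk, the myoblast fusion protein myomaker, by 3.21 (4.06 without WT replicate 1, 2.35 without WT replicate 2), and Emb, the membrane glycoprotein embigin, by 3.16. A dimmer probe set of Emb differed by -0.04. Markers of macrophages and leukocytes moved with these genes, with a median log2 difference of 1.80.

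The genes that fell changed less. Mstn, which encodes the muscle growth inhibitor myostatin, fell from 7.61 ± 0.08 to 5.69 ± 0.48 (SD, n = 2 each; log2 difference -1.92, SE 0.24, adjusted p = 0.0187), which makes WT 3.79-fold higher. Slc40a1, the iron exporter ferroportin, differed by -1.78 (adjusted p = 0.0303), and Asb2, a subunit of a muscle ubiquitin ligase, by -1.64 (adjusted p = 0.0456). Chac1, which degrades glutathione, differed by -1.61 (adjusted p = 0.0494). Mylk2, the skeletal muscle myosin light chain kinase, differed by -1.43 (adjusted p = 0.0152), and Nos1, the nitric oxide synthase held at the muscle membrane, by -1.31 (adjusted p = 0.0494). The enzyme genes Mccc2 of leucine breakdown (-1.45), the alanine aminotransferase Gpt2 (-1.25), the phosphodiesterase Gpcpd1 (-1.36) and the phosphatidate phosphatase Lpin1 (-1.15) were also among them. The chromatin remodeller Smarca1 (-1.23) and the sodium channel subunit Scn4b (-1.16) completed the 12. Quantile normalization ended the calls of Asb2, Chac1, Gpcpd1, Nos1, Smarca1 and Lpin1. Without an intensity filter 7 of the 12 lost their calls, Mccc2 and Scn4b among them (limma adjusted p = 0.0636 and 0.0542). With the replicate number as a block, Mstn and Mylk2 alone stayed called.

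The count without a test also separated the genotypes. At least 1.5-fold differences in every pair of arrays were found for 749 genes higher and 111 genes lower in dbTg, and after quantile normalization for 512 and 196. The same count by replicate number gave 20 and 35 genes, and by the crossed split 19 and 27. Ilf2, Cd226 and Mstn were among the genes counted for genotype.

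Of the 33 gene lists tested, camera called 13 higher and 6 lower in dbTg at the preset correlation. Camera sets a list against the other tested genes. The medians and counts of positive differences given for lists are not corrected for the median of all tested genes. That median was 0.089, and -0.002 after quantile normalization. With an estimated correlation none kept its call, with 4 lists at an unadjusted p under 0.05. That test has 2 residual degrees of freedom and can miss lists that moved, here and wherever its adjusted p is given below. Fry called 9 higher and 0 lower (13 and 0 at an unadjusted p under 0.05). Of fry's 9 lists, 8 were among camera's 13, and the other was the list of endoplasmic reticulum and amino acid stress. Fry did not call the lists of interferon response, microRNA loci, extracellular matrix, proteasome and ribosomal proteins.

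**Figure D2:**
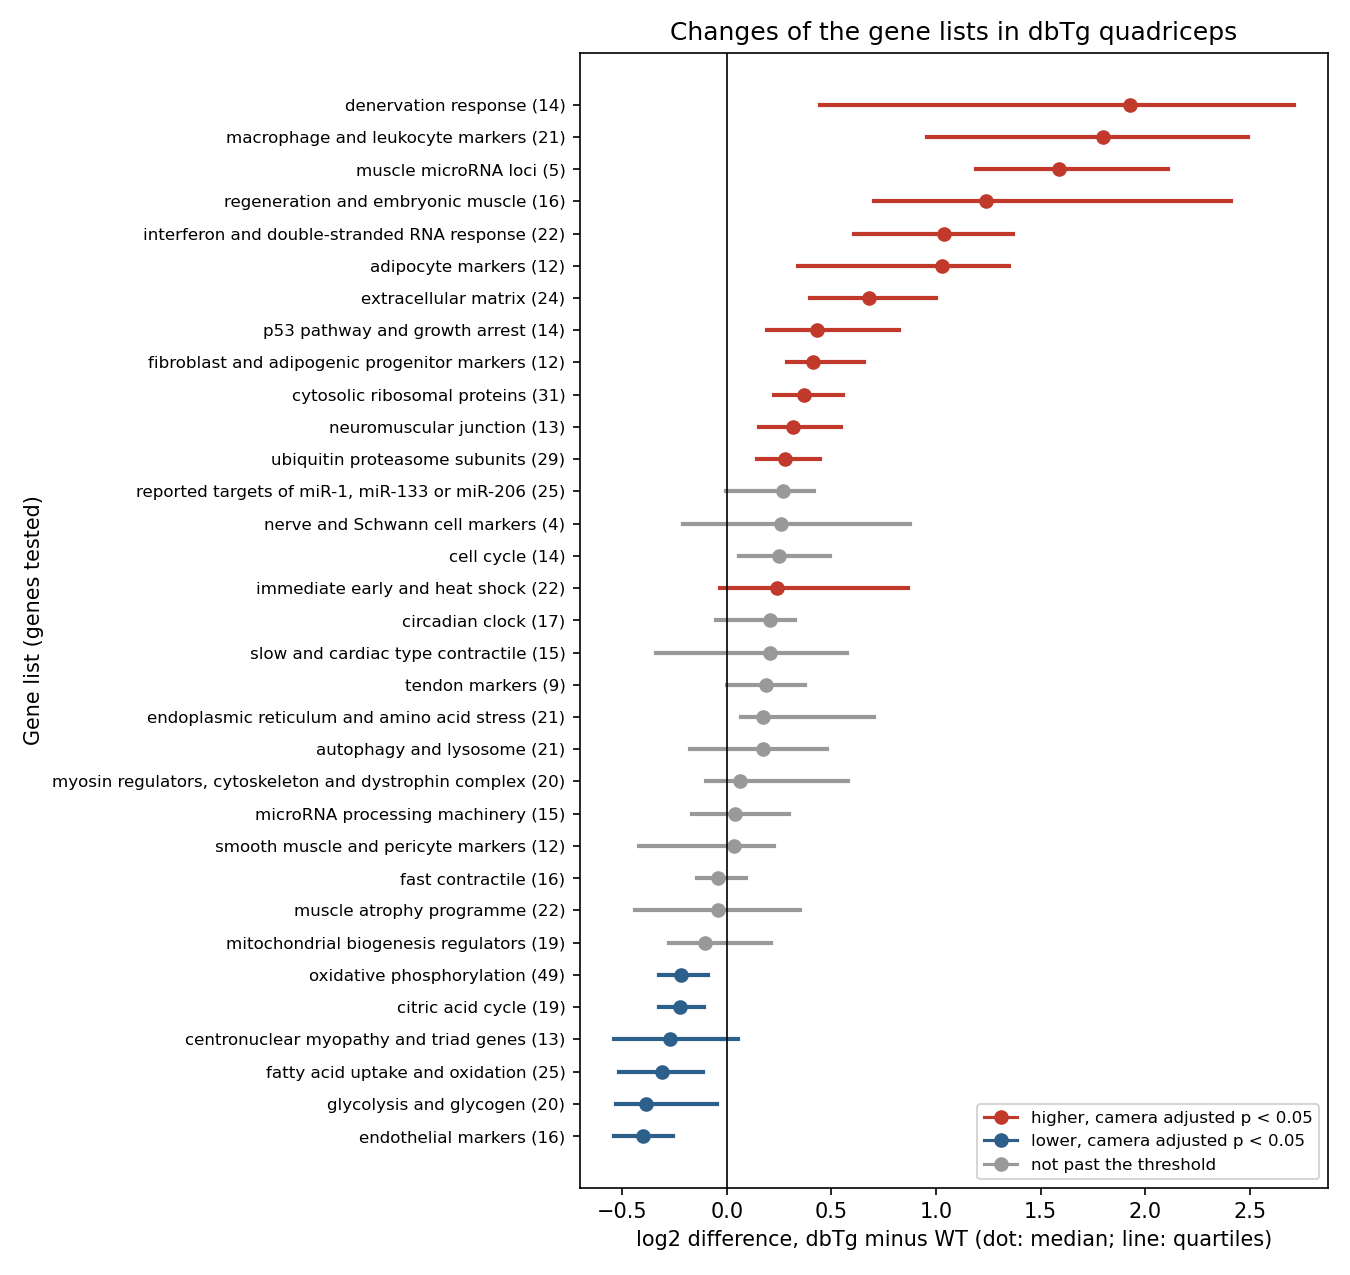
Median log2 difference (dbTg minus WT, horizontal axis; lines span the quartiles over member genes) of the 33 gene lists tested, with the number of genes tested. Colours give camera's call at the preset correlation, with 13 lists higher and 6 lower. The medians run from 1.93 for the denervation list to -0.40 for the endothelial markers.

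Part of the genes that muscle fibres express when they lose their nerve or regenerate were higher. Of 14 tested genes of the denervation response, 6 rose over all genes and 10 adjusted over the list alone, with a median log2 difference of 1.93. Of the other members, 2 had negative differences, and 1 of them, Dach2 (-0.78), was lower at an unadjusted p under 0.05. The list sets no direction for its members, so the difference of Dach2 is not read for or against a denervation response. The median was 1.17 without WT replicate 1 and 2.42 without WT replicate 2, and 2.53 in the male and 1.19 in the female pair. Camera's adjusted p was 3.86e-07, against an adjusted p = 0.364 with an estimated correlation. Ncam1, the neural cell adhesion molecule, rose 8.01-fold, the acetylcholine receptor subunit gene Chrna1 5.72-fold and the transcription factor gene Runx1 6.86-fold. Myog, the myogenic factor myogenin, had a difference of 2.18 and an adjusted p of 0.111. Of 16 genes of regeneration and embryonic muscle, 7 rose over all genes and 13 adjusted over the list alone (14 positive and 2 negative differences; median 1.24; camera adjusted p = 5.91e-09; adjusted p = 0.364 with an estimated correlation). They included Ankrd1, Myh3 and Mymk, the cardiac troponin T gene Tnnt2 (2.45) and the embryonic light chain gene Myl4 (1.36). Macrophage and leukocyte markers, median 1.80, were higher in the same mice. Of 13 genes of the neuromuscular junction, 1 rose over all genes (Chrna1, also in the denervation list) and 3 adjusted over the list alone. Their median was 0.31 (camera adjusted p = 0.0368; adjusted p = 0.377 with an estimated correlation). The junction list lost its call without WT replicate 2 (adjusted p = 0.149) and without dbTg replicate 1 (adjusted p = 0.0639), and with the mean of a gene's probe sets (adjusted p = 0.0514). Its median was 0.52 without WT replicate 1 and 0.50 without dbTg replicate 1.

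The tested muscle microRNA loci were higher in dbTg, as were leukocyte markers (median 1.80) in the same mice. Of 10 listed loci named on the array, 5 passed the intensity filter, which takes the mean over all 4 arrays and so favours loci that rose. The other loci were not tested. Of the tested loci, 3 rose over all genes and 5 adjusted over the list alone (median 1.59; camera adjusted p = 6.11e-05; adjusted p = 0.377 with an estimated correlation). Mir133a-2 rose 5.47-fold (log2 difference 2.45, SE 0.29), Mir133b 4.31-fold (2.11, SE 0.37) and Mir1a-1 3.01-fold (1.59, SE 0.26). All of them code for microRNAs known from striated muscle. Mir133a-2 and Mir1a-1 are neighbours on chromosome 2. The WT means of the 3 loci were low, at 2.34, 1.71 and 2.27. Mir133b and Mir1a-1 lost their calls after quantile normalization (adjusted p = 0.0778 and 0.0715) and without an intensity filter (0.0583 and 0.0503). A whole-transcript array does not tell the mature microRNA from its longer precursors. The listed targets of these microRNAs had 0 of 25 members past the threshold and 0 adjusted over the list alone, with 5 higher and 2 lower at an unadjusted p under 0.05. Their median was 0.27 (camera adjusted p = 0.521). Dnm2, the dynamin gene linked to centronuclear myopathy, differed by 0.21 (adjusted p = 0.675), with a difference of -0.06 without WT replicate 1. The microRNA processing machinery had 0 of 15 members past the threshold, 2 higher and 1 lower at an unadjusted p under 0.05, and 0 adjusted over the list alone (median 0.04, camera adjusted p = 0.805).

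Macrophage and leukocyte markers had the smallest camera p of all lists. Of 21 tested, 13 rose over all genes and 17 adjusted over the list alone (median 1.80; camera adjusted p = 3.1e-16; adjusted p = 0.364 with an estimated correlation). Ctss, Cd68, the leukocyte antigen gene Ptprc (log2 difference 2.79) and the class II antigen presentation gene H2-Aa (2.66) led the list. The neutrophil gene S100a9 differed by -0.06 (adjusted p = 0.945). The interferon and double-stranded RNA response had 0 of 22 genes past the threshold in limma over all genes, and 15 higher adjusted over the list alone and 15 at an unadjusted p under 0.05. Its median was 1.04 (camera adjusted p = 3.03e-07; adjusted p = 0.377 with an estimated correlation). The RNA sensor gene Ifih1 had a difference of 1.36 (adjusted p = 0.0645) and Oasl2 of 2.14 (adjusted p = 0.0652). Ifih1 was called without WT replicate 1 (adjusted p = 0.0259) and Oasl2 without WT replicate 2 (adjusted p = 0.0281). Leukocyte markers moved with this list as well, with the median of 1.80 given above.

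Lists of connective tissue and fat markers were also higher at the preset correlation, beside the same leukocyte markers (median 1.80). Of 24 extracellular matrix genes, 1 rose over all genes and 13 adjusted over the list alone (median 0.68; camera adjusted p = 3.86e-07; adjusted p = 0.377 with an estimated correlation). That gene was Postn, the matrix protein periostin, which rose by 2.65 on the log2 scale (SE 0.38; 3.27 without dbTg replicate 1, 2.02 without dbTg replicate 2). Fibroblast and adipogenic progenitor markers had 0 of 12 members past the threshold, 4 higher at an unadjusted p under 0.05 and 3 adjusted over the list alone (median 0.41; camera adjusted p = 0.00228; adjusted p = 0.377 with an estimated correlation). Dpt and Lum, both matrix proteins of fibroblasts, had differences of 0.74 and 1.34. Without WT replicate 1 both were called (adjusted p = 0.0398 and 0.0266), and Dpt was called after median centring (adjusted p = 0.0486) and with the filter at the 60th percentile (adjusted p = 0.0426). Of 12 adipocyte markers, 3 rose over all genes and 8 adjusted over the list alone (median 1.03; camera adjusted p = 2.5e-05; adjusted p = 0.364 with an estimated correlation). They were the adipokine genes Adipoq (1.47) and Lep (1.31, from a WT mean of 1.26 under the intensity filter) and the desaturase gene Scd1 (1.23). All of these 3, and Postn, lost their calls after quantile normalization (adjusted p of 0.0664, 0.0664, 0.0797 and 0.054).

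Of 16 tested markers of endothelial cells, 15 had negative differences, with 0 past the threshold in limma, 0 adjusted over the list alone and 5 lower and 1 higher at an unadjusted p under 0.05. Their median was -0.40 (camera adjusted p = 3.22e-05; adjusted p = 0.377 with an estimated correlation), and -0.25 without WT replicate 2. Cdh5, the cadherin of endothelial junctions, differed by -0.85 (adjusted p = 0.0929). Smooth muscle and pericyte markers were not called (12 tested, median 0.03, camera adjusted p = 0.234), with Abcc9 at -0.51 and Acta2 at 0.91. Acta2 was at 1.28 and called without WT replicate 1 (adjusted p = 0.021), and at 0.55 without WT replicate 2. Nerve and Schwann cell markers (4 tested, median 0.26, camera adjusted p = 0.861), with Gldn at 1.38 and Pmp22 at 0.71, were not called. Gldn was at 0.86 without WT replicate 1 and at 1.90 and called without WT replicate 2 (adjusted p = 0.00959), and Pmp22 at 1.09 without dbTg replicate 1 and 0.32 without dbTg replicate 2. Tendon markers (9 tested, median 0.19, camera adjusted p = 0.596), with Scx at 1.16 (called without WT replicate 2, adjusted p = 0.0332) and Thbs4 at 1.17 (0.70 without dbTg replicate 2), were not called either. Adjusted over each list alone, 1 nerve and Schwann cell marker and 2 tendon markers were higher. Among red blood cell markers Bpgm alone was tested and differed by -0.30 (adjusted p = 0.511), and by -0.44 to -0.15 when 1 array was left out.

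Energy metabolism lists were slightly lower at the preset correlation. Of 49 oxidative phosphorylation genes, 43 had negative differences, and 0 passed the threshold in limma or adjusted over the list alone, with 5 lower at an unadjusted p under 0.05. The median was -0.22 (camera adjusted p = 5.82e-08; adjusted p = 0.433 with an estimated correlation), and -0.09 without WT replicate 2. The respiratory chain genes Cox5b and Ndufb6 differed by -0.48 and -0.49, and Cox5b by -0.22 with the mean of its probe sets. Of 20 genes of glycolysis and glycogen, 0 passed over all genes and 7 were lower adjusted over the list alone, with 8 lower at an unadjusted p under 0.05 (median -0.39; camera adjusted p = 3.57e-06; adjusted p = 0.377 with an estimated correlation). The median of this list was -0.25 without dbTg replicate 2. The phosphorylase kinase genes Phka1 and Phkg1 differed by -0.77 and -0.82, and Phka1 was called without WT replicate 2 (adjusted p = 0.0432). The citric acid cycle had 0 of 19 genes past the threshold and 3 lower at an unadjusted p under 0.05 (median -0.22; camera adjusted p = 0.000115; adjusted p = 0.377 with an estimated correlation). Ogdh differed by -0.35 and Suclg1 by -0.43. Fatty acid uptake and oxidation had 0 of 25 past the threshold, with 2 lower and 1 higher at an unadjusted p under 0.05 (median -0.31; camera adjusted p = 0.000188; adjusted p = 0.495 with an estimated correlation). Ucp3 differed by -0.63 and Fabp4 by 0.52 (0.34 without WT replicate 1, 0.7 without WT replicate 2). Both of these lists had 0 members adjusted over the list alone. Without WT replicate 2 the citric acid cycle (adjusted p = 0.0684) and fatty acid (adjusted p = 0.31) lists lost their calls, with medians of -0.11 and -0.01. Without WT replicate 1 the fatty acid median was -0.61. Regulators of mitochondrial biogenesis were not called (19 tested, median -0.10, 1 lower adjusted over the list alone, camera adjusted p = 0.0947). Leukocyte markers, median 1.80, moved in the opposite direction to these lists.

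The list of genes of the triad, where the fibre's membrane tubules meet the calcium store, and of centronuclear myopathy was lower at the preset correlation. Of 13 tested, 9 had negative and 4 positive differences, 0 passed over all genes and 1 was lower adjusted over the list alone, with 5 lower at an unadjusted p under 0.05. The median was -0.27 (camera adjusted p = 0.00113; adjusted p = 0.377 with an estimated correlation). It was -0.12 without WT replicate 1, -0.42 without WT replicate 2 and -0.13 without dbTg replicate 2. The calcium release channel gene Ryr1 differed by -0.88 (adjusted p = 0.0597; 0.0483 with the filter at the 60th percentile) and Jph1, a protein that holds the triad together, by -0.49. The myotubularin gene Mtm1 differed by 0.16 (adjusted p = 0.753), and by -0.04 after quantile normalization. Contractile genes were not called as lists. The fast list had Mylk2 lower among 16 genes (median -0.04, camera adjusted p = 0.0937), with an adjusted p of 0.00171 without dbTg replicate 1. The slow and cardiac list had 0 of 15 past the threshold, 2 higher and 1 lower at an unadjusted p under 0.05 (median 0.20, camera adjusted p = 0.861). Without WT replicate 1 it was called lower (median -0.75, adjusted p = 0.00786), and without WT replicate 2 higher (median 1.17, adjusted p = 0.00195). Of 20 genes of myosin regulators, the cytoskeleton and the dystrophin complex, Xirp1 (1.27) and Flnc (0.83), both actin-binding proteins of fibre repair, rose. That list was not called (median 0.06, 4 higher adjusted over the list alone, camera adjusted p = 0.331), and had an adjusted p of 0.0355 without an intensity filter.

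The muscle atrophy list was not called (22 tested, median -0.04, mean 0.05, camera adjusted p = 0.201), with 2 members higher and 1 lower adjusted over the list alone. Mstn fell, and the ubiquitin ligase genes Fbxo32 and Trim63 had differences of -0.82 (adjusted p = 0.291) and -0.27 (adjusted p = 0.846). Without WT replicate 1 the list was called lower, with a median of -0.40 and an adjusted p of 0.000101, and without WT replicate 2 higher (0.35, adjusted p = 0.043). Autophagy and lysosome genes were not called (21 tested, median 0.18, camera adjusted p = 0.358; adjusted p = 0.0348 without an intensity filter), with Ctss the 1 member past the threshold over all genes. Adjusted over the list alone, 4 of them were higher and 1 was lower. Proteasome subunits had 0 of 29 past the threshold or adjusted over the list alone, and 6 higher at an unadjusted p under 0.05. Their median was 0.28, with Psmc4 at 0.54 and Psmd6 at 0.60 (camera adjusted p = 0.0068; adjusted p = 0.433 with an estimated correlation). The proteasome call was lost without WT replicate 2 (adjusted p = 0.0684) and without dbTg replicate 1 (adjusted p = 0.11, median 0.17). Of 31 cytosolic ribosomal protein genes, Rpl19 rose (0.91), and 3 were higher adjusted over the list alone (median 0.37; camera adjusted p = 0.000125; adjusted p = 0.377 with an estimated correlation). The other probe set of Rpl19 differed by 0.04.

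Stress genes moved in part. Of 14 genes of the p53 pathway and growth arrest, 2 rose over all genes and 2 adjusted over the list alone (median 0.43; camera adjusted p = 0.0175; adjusted p = 0.377 with an estimated correlation). They were the death receptor gene Eda2r (2.69; 3.32 without WT replicate 1, 2.06 without WT replicate 2) and Mdm2 (0.88), which restrains p53. That list lost its call without dbTg replicate 1 (adjusted p = 0.0784) and with the filter at the 60th percentile (adjusted p = 0.0657). Of 22 immediate early and heat shock genes, 2 rose over all genes and 7 adjusted over the list alone (median 0.24, and 0.38 without WT replicate 1; camera adjusted p = 0.0217; adjusted p = 0.377 with an estimated correlation). They were the small heat shock protein gene Hspb1 (2.54; its other probe set 0.66) and the stress-induced factor gene Atf3 (2.78). In the list of endoplasmic reticulum and amino acid stress, Ddit3 (2.16) and Atf3 rose and Chac1 fell among 21 genes, and 7 were higher and 1 lower adjusted over the list alone. Camera did not call that list (median 0.18, adjusted p = 0.0876). Its adjusted p was 0.0368 without dbTg replicate 2, 0.00504 without an intensity filter and 0.0276 under fry. Cell cycle genes had 0 of 14 past the threshold and 3 higher at an unadjusted p under 0.05 (median 0.25, camera adjusted p = 0.23). Circadian clock genes had 0 of 17 past the threshold and 0 at an unadjusted p under 0.05 (median 0.21, camera adjusted p = 1), with Clock at 0.33 and Dbp at 1.17. Dbp was at 2.13 and called without WT replicate 1 (adjusted p = 0.00575), and at 0.22 without WT replicate 2. The WT arrays lay far apart for some clock genes. WT replicate 2 was above WT replicate 1 by 2.83 for Nfil3 and 2.26 for Arntl, while Nr1d1 and Bhlhe41 differed by -2.74 and -2.72. With such a spread in WT, changes of clock genes could be missed. Leukocyte markers, median 1.80, were higher in the same mice.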

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

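The tests of neighbouring genes of the microRNA loci, of genes bright over all 4 arrays, of other leukocyte genes and of chromosome 18 were fixed before their results were seen. The remaining tests here were chosen afterwards.

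Some lists and 1 gene moved in opposite directions in the male and the female pair, with 1 array per sex and genotype, so these differences were not tested. The female minus male gap in the median log2 difference was -0.93 for the muscle atrophy list (0.43 in males, -0.50 in females). It was -0.91 for the slow and cardiac contractile list (0.50 and -0.41), -0.12 for the fast contractile list and -0.25 for the list of myosin regulators, cytoskeleton and dystrophin complex. It was 0.48 for tendon markers and 0.38 for the circadian clock. Among named genes, the clock output factor gene Dbp differed by -0.13 in males and 2.47 in females, a gap of 2.60. The slow-fibre myosin gene Myh7 was read at 2.30 and 1.62 in the WT and dbTg males and 6.29 and 5.33 in the females.

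Signal also appeared in probe sets outside the gene comparison. Of 5 probe sets that pair only with several immunoglobulin genes, 3 were at least 2 higher on the log2 scale in dbTg than in WT, and the largest rose from 1.43 to 7.82. Among probe sets without exactly 1 gene symbol, 179 were at least 2-fold higher and 69 lower in every pair of arrays, where the split by replicate number gave 78 in all.

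Most called genes were higher in dbTg, leukocyte markers among them. A lower share of fibre RNA alone would raise the markers of all other cell types alike, but the leukocyte median exceeded the endothelial median by 2.20, with quartiles that did not meet. These were the cell type lists furthest apart. The adipocyte, fibroblast and smooth muscle medians were 1.03, 0.41 and 0.03. A lower share of fibre RNA together with changes of single cell types was not excluded. That values near the floor of the array cannot fall, which would leave bright genes evenly split, cannot be told apart from other sources. Of the 221 called genes bright over all 4 arrays 89.1% were higher (Wilson 95% interval 84.4 to 92.6), but 82 of the 197 higher ones were in this part by rising. By the level in WT the share was 82.6% (75.7 to 87.8) of 149 called genes at or above the median, 69.0% (57.5 to 78.6) of 71 above the upper quartile and 48.5% (32.5 to 64.8) of 33 above the 90th percentile. More leukocyte RNA remains open and may account for part of the rise of Ctss, Ptprc and Cd68 (7.29, 4.83 and 6.36 in dbTg), since 22 of 25 other leukocyte genes, 21 of the 25 above the filter in WT, had positive differences, with a median of 0.75 (quartiles 0.32 and 0.97). Of the 25, 3 passed the threshold and Fermt3 differed by -0.61, and the median lay under the differences of Ctss, Ptprc and Cd68 (4.23, 2.79 and 3.76). A change within resident leukocytes and an effect of the genotype on the fibres remain open and untested, and 14 of the 267 higher genes belong to the lists of denervation, regeneration, junction and cytoskeleton, 16 to the leukocyte lists and 237 to neither.

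The 5 tested of 10 measured muscle microRNA loci were higher in dbTg. Their median of 1.59 lay above that of all 10000 random lists of equally bright genes, which leave out the correlation between members. The list was not called with an estimated correlation (adjusted p = 0.377) or under fry (adjusted p = 0.0818). A shift of all microRNA probe sets was set against the other 144 tested, whose median was 0.10 (quartiles -0.18 and 0.45), below the lower quartile of the list. The 61 of these brighter than the filter by at least 1 in either group had a median of 0.29 and an upper quartile of 0.66, also below it, which argues against a general shift. Changed transcription of the neighbours cannot be told apart from other sources: the 8 nearest tested genes had a median of 0.14 (quartiles -0.05 and 0.44), but 6 of them lay less than 1 above the filter in both groups. The brighter ones were Mib1 (0.41) and the long noncoding RNA gene B230312C02Rik beside Mir1a-1 and Mir133a-2, which differed by 1.19 (95% interval 0.203 to 2.18, adjusted p = 0.19). More transcription of the loci and slower processing of their precursors in dbTg muscle may each be the source and were not tested.

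Cd226 had the largest measured difference of the called genes, from a WT mean of 1.35 that lay under the filter. RNA of T cells, natural killer cells or platelets would bring their other markers. Of these, 15 had a median difference of 0.0305 (quartiles -0.13 and 0.12), and the largest rise among them was 0.51. All 15 lay less than 1 above the filter in both groups and 8 were under it on average. No marker was bright enough in either group to show that its probe set responds. These markers therefore do not decide whether such cells brought Cd226. The 7 tested had a median of 0.07. The 15 markers were chosen after their values were seen, and they leave out macrophages. Macrophage and leukocyte markers had a median difference of 1.80, and such cells as a source of Cd226 were not tested. A change of the whole region would move its other genes, but the largest difference among the 5 nearest named genes was 0.41. Cbln2, Rttn and Dok6 of these lay less than 1 above the filter in both groups. The brighter Tmx3 and Socs6 had upper 95% bounds of 0.902 and 0.868, which argues against a change of 1 or more at these genes. Socs6 was that bright in dbTg only (2.56, against 2.20 in WT). Both were higher in both dbTg arrays, by 0.41 and 0.36 on average, so a smaller change of the region was not excluded. A segment of chromosome 18 that differs between the groups cannot be told apart from other sources: 8 of 323 tested genes there were called, without Cd226 and the family of Iigp1 (odds ratio 1.14, 95% interval 0.484 to 2.31, Fisher's exact test p = 0.697), and the interval is wide. An altered Cd226 gene alone, such as by an inserted transgene, may also be the source and was not tested.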

How the results depend on the processing

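All alternatives here were planned before the data were examined. Calls rest on the spread between 2 arrays per group: the dbTg arrays lay closer together (median absolute log2 difference 0.198) than the WT arrays (0.251), and without an array the spread comes from the other group's pair. Leaving out 1 array gave 4 to 610 higher and 0 to 156 lower genes, 1157 to 1436 genes at least 1.5-fold higher and 238 to 474 lower in every pair. Without either dbTg array the shared calls were 4, and without either WT array 292 of the 294. The replicate block left 63 higher and 2 lower genes, with 1 residual degree of freedom. It ended the calls of 24 of the 46 called named genes, including 10 of the 12 named lower genes (all but Mstn and Mylk2), gave 185 genes at least 1.5-fold lower and changed no list's call. The labels give no pairing of the animals by number beyond their sex. The correlation of the within-group differences was 0.0486 across genes, which does not exclude a difference by number shared by part of the genes. The slow and cardiac list was higher in replicate 2 of both groups (medians 2.22 in WT and 0.86 in dbTg), with 12 of 15 tested genes higher in both.

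Quantile normalization gave 120 higher and 7 lower genes (94.5% higher), all 127 among the 294, and 512 genes at least 1.5-fold higher and 196 lower. Without an intensity filter 165 were higher and 7 lower, over 22180 genes. The filter at the 60th percentile gave 44 lower and eBayes without a trend 14 lower. An adjusted p under 0.10 gave 646 and 126. Every probe set on its own gave 5 and 0 (1087 lower at an unadjusted p under 0.05), and the t-test without moderation gave 2 and 0 (408). For the count in every pair, a 2-fold limit gave 258 higher and 13 lower. Called lists fell to 0 higher and 0 lower with an estimated correlation, and fry left 0 lower. Beyond the changes of construction (fewer arrays, more genes, another limit), the cause was not tested. Of the 46 called named genes, 17 lost their call after quantile normalization (Mymk, Asb2, Chac1, Gpcpd1, Nos1, Smarca1, Lpin1, Myl4, Mir1a-1, Mir133b, Flnc, Postn, Adipoq, Lep, Scd1, Mdm2 and Rpl19), 14 without a filter, 9 without a trend, Rpl19 with the mean of a gene's probe sets and Sln with robust eBayes. Median centring, the mean of a gene's probe sets, robust eBayes and a 1.5-fold minimum kept both counts within 1.5 times.

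None of the 46 called named genes and 19 called lists changed direction. Among uncalled genes, leaving out 1 array moved Dnm2 between -0.0568 and 0.484 and Xist between -2.41 and 3.03, and quantile normalization moved Mtm1 to -0.0434. For lists, the direction is camera's, relative to other genes, and can differ in sign from the median: camera leaned down for the slow, clock, smooth muscle and microRNA processing lists, whose medians were above 0. Camera's direction turned for some uncalled lists when 1 array was left out. Their medians then ranged from -0.399 to 0.351 (atrophy), -0.749 to 1.17 (slow), 0.0924 to 0.353 (microRNA targets), 0.0179 to 0.512 (nerve), -0.0625 to 0.433 (tendon) and 0.0529 to 0.298 (clock). It also turned after quantile normalization for the slow list (0.0277) and the clock (0.048). Without a filter it turned for the slow list (0.124), microRNA processing (-0.0118), nerve markers (-0.109) and the clock (0.208). Under fry it was up for the slow list (0.204), microRNA processing (0.0396) and the clock (0.208). The cause was not tested. With no background level in the values used here, signal over background limits what can be said of genes near the filter at 1.48.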

Other observations

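The list of plasma cell genes was chosen before its values were seen, and the other choices below were made afterwards, in part on genes already seen to change.

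Some genes that interferon gamma induces, chosen in part because they had been seen to rise, were not in the fixed interferon list. Of 24 tested genes for interferon-inducible GTPases, antigen presentation and chemokines, all had positive differences and 8 rose over all genes, with a median of 1.09 on the log2 scale. Iigp1 rose by 3.46, the chemokine gene Cxcl9 by 2.59, Gbp10 by 2.48, Igtp by 2.26 and Irgm2 by 2.06. B2m, the light chain of class I molecules, rose by 1.65. The GTPase genes lie on several chromosomes, and Iigp1 and its relatives Gm4841 (4.30) and Gm4951 (2.75), which rose as well, lie on chromosome 18. Leukocyte markers moved with them (median 1.80). Of the plasma cell genes, Jchain, which joins secreted antibodies, rose by 1.17, and the median of the 5 tested was 0.02 (-0.09 without WT replicate 1, 0.14 without WT replicate 2). Jchain passed the filter through its dbTg level (mean 2.26, against 1.09 in WT). The median over all 11 measured plasma cell genes was -0.06.

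Of 18 tested genes of branched-chain amino acid breakdown, 16 had negative differences and 2 fell over all genes, Mccc2 (-1.45) and Bckdk (-0.91), the kinase that switches the pathway's central enzyme off. The median was -0.46 (p = 0.174 with an estimated correlation and 0.161 under fry). It was -0.20 in the male pair, with 5 positive differences, and -0.78 in the female pair, with 1 array per sex and genotype and no test of this gap, and -0.25 without WT replicate 2. WT replicate 2 read higher than WT replicate 1 by a median of 0.49 over these genes, while Mccc2 and Bckdk were lower in both pairs. Sterol synthesis genes had a median of 0.16 over 17 tested (0.09 without WT replicate 1), with Fdft1 the 1 gene past the threshold, at -0.92. Among microRNA genes outside the muscle list, Mir27a (2.17) and Mir23a (1.67), which share a cluster, Mir692-1 (1.44) and Mir703 (1.33) rose, and Mir1904 differed by -1.21 and fell.

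The WT arrays differed from each other more than the dbTg arrays did. Between the WT arrays 491 genes were at least 2-fold apart, and between the dbTg arrays 142. In WT replicate 2 against WT replicate 1 the growth arrest gene Cdkn1a was 3.37 higher and the metallothionein gene Mt2 2.85 higher, and the glycolysis regulator gene Pfkfb3 differed by -3.41 and the clock gene Nr1d1 by -2.74. In dbTg the same differences were 0.41, -0.37, 0.49 and 1.35. The slow and cardiac list was higher in replicate 2 than in replicate 1 of both groups, with medians of 2.22 in WT and 0.86 in dbTg.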
